A study of Mus musculus with 8 samples.

How the data were processed

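Left ventricle RNA of 8 male C57Bl/6j mice, an inbred laboratory strain, was measured on 2-colour Agilent mouse expression arrays. Per the labels, the mice ate normal chow with 0.4% sodium or a low salt diet with 0.05% sodium for 8 weeks and were killed at 16 weeks of age, with 4 mice in each diet group. The whole ventricle sampled (septum, free wall, apex) was homogenised, total RNA was amplified and labelled with Cy3 or Cy5, and spike-in RNA was added as a positive control, per the labels' protocols. There were 4 arrays, all on 1 slide and read in 1 scan run. Each array carried 2 mice of the same diet, one in each dye, so that diet differed between arrays and dye differed within them. Both arrays of a diet lay side by side on the slide, and the place on the slide and the diet cannot be told apart.

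The scanner tables hold the intensity of each spot and of its local background per channel as read from the image, per the file headers, which name Agilent Feature Extraction 11.5.1.1 with the protocol GE2_1105_Oct12. The tables of the 2 samples of an array are identical copies, and the channel of each sample was taken from its dye. The scanner software's own processed intensity is, per the file headers, background-subtracted, corrected for a spatial trend and dye-normalised within the array. The deposited value table of the whole series holds a ratio. Each column equals the median signal minus the background median, divided by the median of that difference over the spots the column holds. The table holds 42930 to 42991 values per Cy3 sample and 30259 to 32500 per Cy5 sample. Its columns all have a median of 1, and 100% of its values were found in the scanner column of the same sample, while between 0.137% and 0.375% stood at the row of the same number. Its rows could therefore not be named, and it was not used for any gene. How its rows were ordered stays unknown.

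Each array holds 44397 spots, of which 43020 are not controls and carry 39429 probes. The median spot intensity lay between 116 and 147 over the samples, against a median background between 15.5 and 33.5. Between 53.0% and 66.3% of the non-control spots were well above background, and 1 spot was saturated in 1 sample, with 0 in the others. The number of arrays limits the precision of every value given. Probe names follow the accession in the array design where the RefSeq gene table given for mouse holds it, which named 27502 probes, with 3551 named by gene name and 398 by a synonym. The other 7978 probes kept the name in the file. Coordinates are those of the array design on the mm9 build; no exon or untranslated region is given for a probe.

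Mean signal and background median were corrected with normexp (offset 50), normalised by loess within each array and by Aquantile between arrays, and turned into log2 values per channel, in limma 3.58.1 under R 4.3.3 with statmod 1.5.0. A departure from the plan was needed. Where the local background carried an outlier flag, its value could exceed the spot by a wide margin and the normexp fit failed to settle, so the channel's median background took its place there and normexp was fitted per channel on spots whose own signal was not flagged. Control spots had weight 0 in the loess curve and were then left out, as were flagged spots. Spots of 1 probe were averaged. Probes well above background in at least 4 samples were kept, and each gene was read from its brightest probe, which left 18093 genes, counting unnamed transcripts.

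The linear model in limma held diet and dye as fixed terms and array as a random block through duplicateCorrelation, followed by empirical Bayes moderation and Benjamini-Hochberg adjustment over all genes, with a threshold of 0.05 and 2-sided tests. Differences are low salt minus normal salt on the log2 scale. The 32 gene lists (pathways of the heart, salt and hormone pathways, and markers of other cell types) were tested with cameraPR on the moderated statistic with a preset inter-gene correlation of 0.01, and again with a correlation estimated from the residuals of each list and with fry. Of 782 list entries 778 matched a gene of the array. A further result with no test counted the genes at least 1.5-fold apart in the same direction in the Cy3 samples and in the Cy5 samples. For a gene not well above background in any sample of a group, a fold is a bound against the lowest signal among probes well above background in each sample.

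Named genes were the 12 largest rises and the 12 largest falls past the threshold among genes with a proper symbol and the same sign in both dyes, a few members of each list by smallest p, and a set of salt, ion transport and natriuretic genes named whatever their result. In each list these were up to 4 members past the threshold, or the 2 with the smallest p where there were none. Arhgef19, Bag1, Eif4enif1, Gorasp1, Lsmem1 and Scx were added after their values were seen, as were the clock genes other than Nr1d1 and the list members in the text that this rule did not name. The design, this rule, the lists and the alternatives were fixed before the data were examined, apart from those said to be chosen later.

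A local trend was computed after the data had been seen. For each spot and sample it is the median, over the spots within 10 rows and 3 columns, of the sample's difference from the spot's mean over all samples, with a median of 82 spots in a window. A part of the arrays is called uneven where this trend passed 0.2 in size in any sample. Genes were then tested again on even parts alone, and after the trend had been subtracted.

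The labels number the mice 1 to 4 in each diet. Deviations from the group means of mice with the same number correlated at 0.305, 0.141, 0.162 and 0.193. Each normal salt mouse correlated best with the low salt mouse of its number, so the numbers were treated as pairing the samples. Same-numbered mice share a dye, and with means taken within dye the correlations were 0.208, 0.106, 0.208 and 0.106. With 2 mice of a diet in each dye, mice 1 and 3 must give the same value, as must mice 2 and 4. The pairing comes from the data: a number shares its dye and its array number in the labels, and the labels state no common litter or day. Fits with the number as a block are given where they change a call. Calls that need this block rest on a pairing that cannot be told apart from a shared dye and array number.

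The scripts were tested on simulated arrays with the real spot means, spreads and array correlation. In these, 200 of 18093 genes were changed between the diets, and the other members of the renin-angiotensin list were raised by 0.5. Errors were drawn independently between genes. Of genes changed 1.5-fold 37.3% were called, against 82.1% of those changed 2-fold and 98.5% of those changed 3-fold, and 7.55% of the calls had no change. The raised list passed in cameraPR with the preset correlation (adjusted p = 1.025e-15), and 1 other list was called as well. With no change at all 0 genes and 0 lists were called. A patch brighter by 0.8 on the low salt arrays, with no change in any gene, gave 448 calls, of which 0 remained when even parts alone were tested. In the full fit 94.7% of the risen calls lay in uneven parts, so some false calls lay in even parts.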

Results

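The series compared gene expression in the left ventricle of male mice after 8 weeks on normal (0.4% sodium) or low salt (0.05% sodium) chow, with 4 mice in each group. The question, as the series states it, is how dietary salt alters expression in the heart. Normalised log2 intensity was available for 18093 genes in all 8 mice. Intensities of 2 mice on the same array correlated across genes at 0.994 to 0.996, those of mice of the same diet on different arrays at 0.983 to 0.991, and those of mice of different diets at 0.980 to 0.990. The first principal component held 35.7% of the variance and separated the diets, and the second held 27.2% and separated the arrays of each diet. The array correlation in the linear model was 0.565.

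Cyp1a1, which encodes a cytochrome P450 enzyme induced through the aryl hydrocarbon receptor, fell furthest among genes past the threshold, from a log2 intensity of 8.81 ± 0.32 (SD, n = 4) on normal salt to 6.80 ± 0.14 (n = 4) on low salt. The difference was -2.01 ± 0.21 (SE; limma adjusted p = 0.00408), a 4.04-fold lower signal, and all 4 low salt mice lay below all 4 normal salt mice. Its probe was well above background in 4 normal salt and 2 low salt mice, and with the scanner's processed signal the difference was -3.51, so the size of the fall depends on the processing. Nr1d1, the nuclear receptor that represses Arntl in the circadian clock, rose from 9.62 ± 0.24 to 10.72 ± 0.20, a 2.15-fold higher signal (SE of the log2 difference 0.10; adjusted p = 0.00300), with all 4 low salt mice above all 4 normal salt mice. Nmb, which encodes neuromedin B, fell 2.38-fold, from 10.58 ± 0.20 to 9.32 ± 0.25 (adjusted p = 0.0336), and the log2 difference of its second probe was -1.21. Scx, which encodes the tendon and valve transcription factor scleraxis, rose from 10.13 ± 0.11 to 11.13 ± 0.25 (adjusted p = 0.0330). Without any 1 mouse other than low salt mouse 3 both calls ended, at adjusted p values between 0.0685 and 0.118 for Nmb and between 0.0650 and 0.106 for Scx, and on even parts alone they were 0.0949 and 0.101.

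The Cyp1a1 probe lies on chromosome 9 from 57551535 to 57551594 in mm9 and has the sequence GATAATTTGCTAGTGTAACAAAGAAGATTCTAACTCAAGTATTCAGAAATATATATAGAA. The Nr1d1 probe, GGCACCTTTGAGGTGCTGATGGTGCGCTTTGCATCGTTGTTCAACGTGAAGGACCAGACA, lies on chromosome 11 between 98630526 and 98631028, a span longer than the probe. Both stood in parts of the arrays with an even signal. These calls of Cyp1a1 and Nr1d1 held in 18 of the 19 alternatives run for single genes. The exception averaged each array to 1 value, where the adjusted p was 0.125 for Cyp1a1 and 0.143 for Nr1d1. No gene passed in limma with Cy3 samples alone, Cy5 samples alone or no normalization between arrays, where 1848, 1244 and 779 genes had an unadjusted p under 0.05.

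Across all genes 137 rose and 7 fell past the threshold, and 1985 had an unadjusted p under 0.05. Without the array of low salt mice 3 and 4 the balance turned, with 456 up and 655 down. That fit leaves low salt with 1 array, so array and diet cannot be told apart in its calls. With the mouse number as a block, 228 genes changed. Without normal salt mice 1, 2 and 3 in turn the count was 71, 64 and 53, and without low salt mice 1 to 4 it was 57, 57, 71 and 52. The risen genes moved by 0.55 to 1.78, with a median of 0.89. Of the 137, 129 had their probe where the signal was uneven over the arrays, which held 27.3% of all genes tested. These probes gathered at the left edge, mostly between rows 142 and 265 and columns 3 and 14. Where the local difference passed 0.2, local medians ranged from -0.16 to -0.30 in normal salt samples and from 0.17 to 0.24 in low salt samples. These medians are relative to the mean of all samples, so they cannot tell bright low salt arrays from dim normal salt arrays. Tested on the even parts alone, an alternative chosen after seeing the data, 3 genes rose and 1 fell: Nr1d1, Eif4enif1 and the unnamed transcript NAP092202-001, and Cyp1a1.

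**Figure D1:**
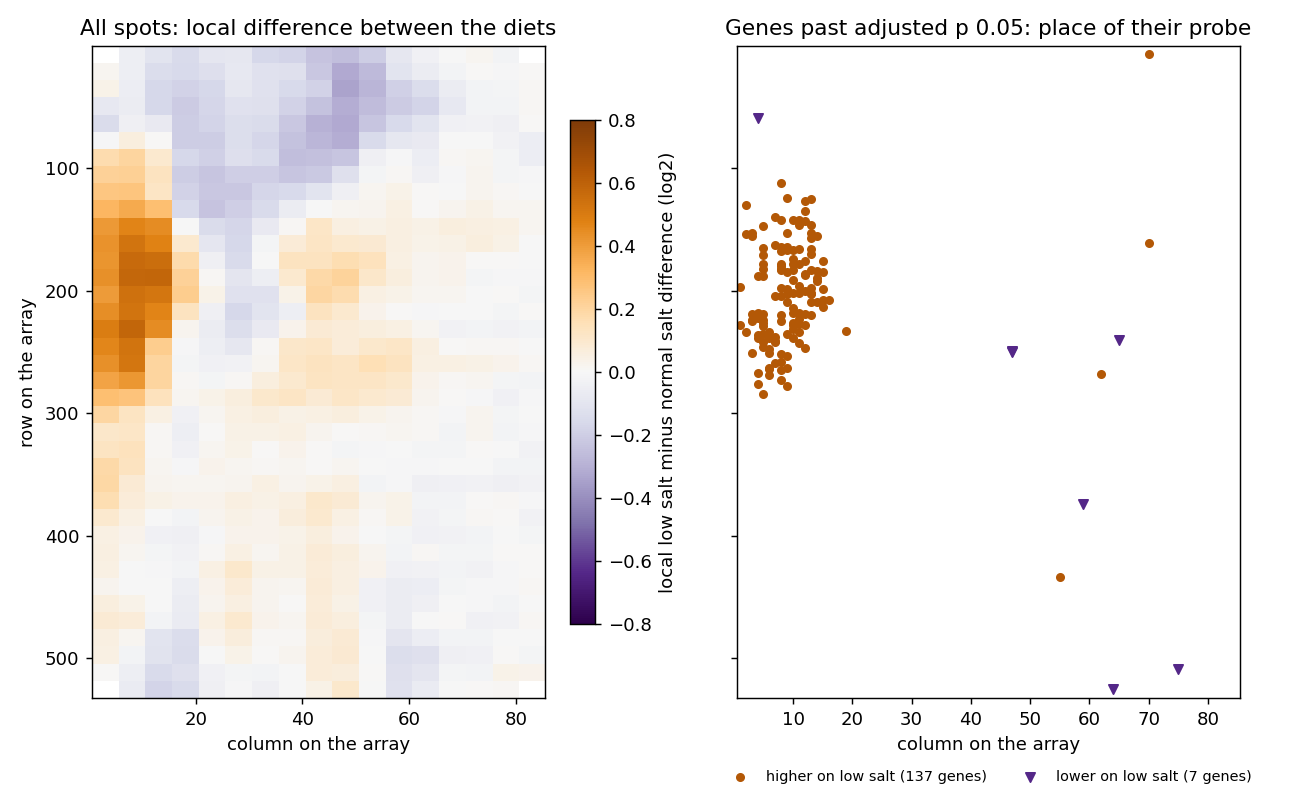
The left panel maps the local low salt minus normal salt difference (log2) over the array, with column and row of the spot on the axes, and the right panel marks the place of the probe of each gene past an adjusted p of 0.05. Most of the 137 genes higher on low salt (circles) lie at the left edge, where the local difference is also high, while the 7 lower genes (triangles) lie in even parts.

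The largest named rises all came from that region. Ddx25, an RNA helicase gene, rose by 1.57, Tmem60 by 1.42, Eif4e, the cap-binding translation factor, by 1.41, Spryd4 by 1.39 and Tsg101, a component of the ESCRT sorting machinery, by 1.37. Tnfaip1, Frmd4a, Ralgapa2, Lin37, Mrpl15, Mrpl46 and Gpr146 rose by between 1.23 and 1.36. All of these had adjusted p values of 0.00408 or less. With the local trend subtracted the 12 values fell to between 0.71 for Mrpl46 and 0.96 for Ddx25, where 10 still passed (adjusted p between 0.00927 for Ddx25 and 0.0268 for Tnfaip1) and Mrpl15 (0.0529) and Mrpl46 (0.0886) did not. Second probes in even parts read less, 0.48 for Eif4e and 0.02 for Mrpl15. Those of Frmd4a read 0.19 and 0.37 and those of Ralgapa2 -0.29 and -0.05. The probes of these last genes were dim, at mean log2 intensities of 6.72 to 7.71. Among members of the fixed lists, Rpl35 of the ribosome rose by 1.05, while another Rpl35 probe in an even part read -0.64, and Rcan1 and Ppp3ca of calcineurin signalling rose by 0.88 and 0.85, also from the uneven region. None of these 3 passed with the local trend subtracted, where Rpl35 read 0.49 (adjusted p = 0.107), Rcan1 0.43 (adjusted p = 0.212) and Ppp3ca 0.35 (adjusted p = 0.132). Without any 1 mouse other than normal salt mouse 4 the call of Rcan1 ended (adjusted p between 0.0951 and 0.124). That of Rpl35 ended without any but normal salt mouse 1 or low salt mouse 3 (adjusted p between 0.0504 and 0.0823).

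The 7 falls all lay in even parts. Besides Cyp1a1 and Nmb they comprised Zfp612 (-0.84), Mthfd1l (-0.81), the coagulation factor gene F8 (-0.63), 4930527J03Rik (-0.75) and Olfr1423. Olfr1423, an olfactory receptor gene, was well above background in 4 normal salt and 0 low salt mice, so its signal was at least 1.76-fold lower on low salt (adjusted p = 0.0211). The low salt mean of 4930527J03Rik was 6.42, close to the 6.41 of Olfr1423, so the size of its fall is limited by signal as well. The probes of F8 and Olfr1423 stood in adjacent rows, 249 and 250, of column 47. The local trend is a median over many spots and cannot show a fault limited to a few. The falls of F8 and Olfr1423 may therefore not be separate. The second probe of Mthfd1l read -0.55 and was dim, at a mean log2 intensity of 6.98. Without 1 mouse, whichever it was, the calls of F8 and Mthfd1l ended, as did those of Zfp612 without any but normal salt mouse 4 and of Olfr1423 without any but mouse 3 of either diet (adjusted p values between 0.0504 for Olfr1423 and 0.134 for Zfp612). Rises in even parts besides Nr1d1 and Scx were Eif4enif1 (1.02), Gorasp1 (0.76), Bag1 (0.67), Lsmem1 (0.63), Arhgef19 (0.60) and NAP092202-001 (0.89). Eif4enif1, Gorasp1 and Bag1 stood between rows 124 and 127, at the border of the uneven region, with local differences of 0.28, 0.15 and 0.22. A second Gorasp1 probe in an even part read 0.24. A second Arhgef19 probe in an uneven part read -0.03 and was dim, at a mean log2 intensity of 7.07. The calls of Arhgef19, Bag1 and Lsmem1 ended without 1 mouse, whichever it was (adjusted p at least 0.0618 for Arhgef19, 0.0769 for Bag1 and 0.0742 for Lsmem1), and that of Gorasp1 without any but normal salt mouse 4 (adjusted p at least 0.0608). Simulated arrays with a bright patch and no change had 94.7% of their risen calls in uneven parts, with the rest in even parts. A call in an even part therefore does not clear a gene of the uneven signal.

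**Figure D2:**
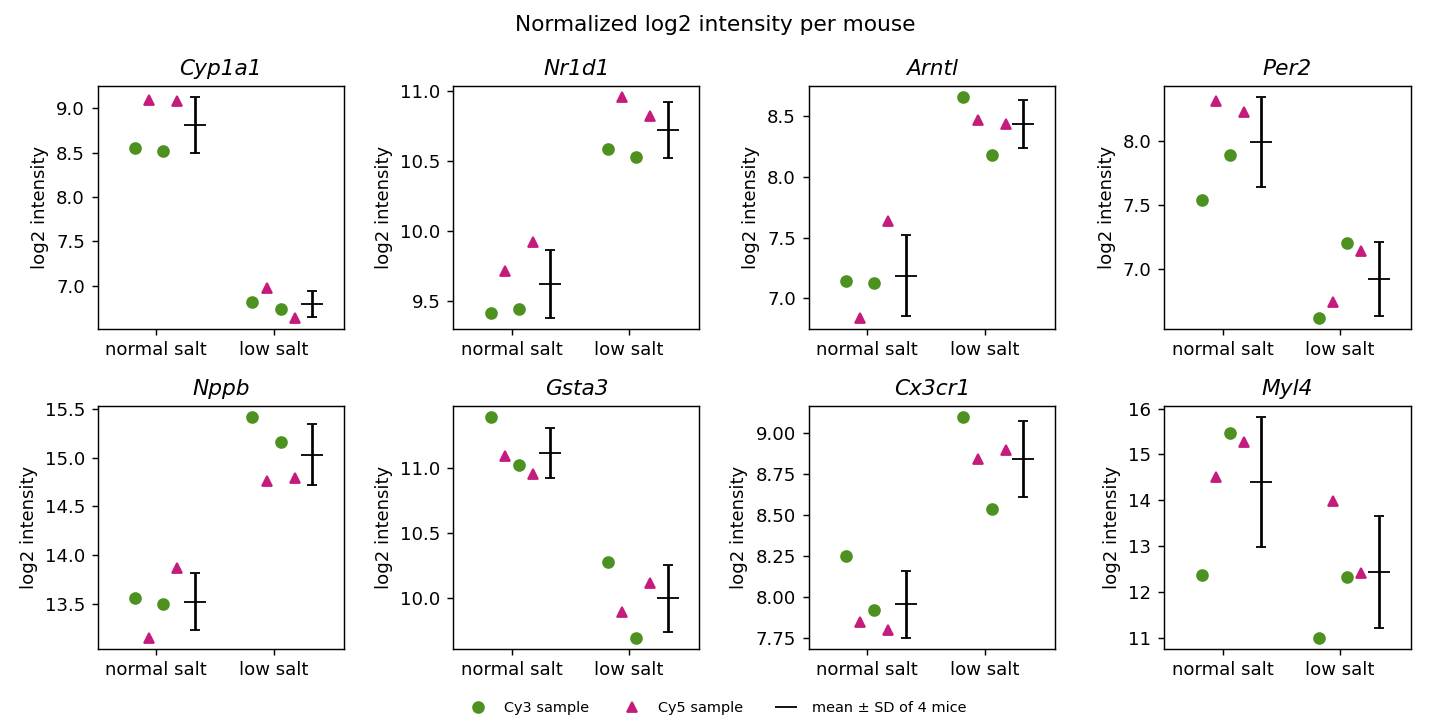
Each panel plots the normalised log2 intensity of 1 gene per mouse, with Cy3 samples as circles, Cy5 samples as triangles and the mean ± SD of 4 mice as a bar beside them. In Cyp1a1, Nr1d1, Arntl, Per2, Nppb, Gsta3 and Cx3cr1 the 4 low salt mice do not overlap the 4 normal salt mice, and in Myl4 mice of both diets overlap; Cyp1a1 and Nr1d1 alone among these passed the adjusted threshold.

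Endothelial markers were lower on low salt, with a median log2 difference of -0.31 and a mean of -0.29 over 18 measured genes, 15 of them lower (cameraPR adjusted p = 0.00415). This was 1 list of 32 past the threshold. With an estimated correlation, 0.561 for this list, its adjusted p was 0.999 (unadjusted p = 0.202), and 0 of the 32 lists passed. The list's 12 members in even parts had a median of -0.23. Eng, a co-receptor for TGF-beta, read -0.49, and Esam, a junction protein gene, -0.59. The angiopoietin receptor gene Tek read -0.71 and the fatty acid carrier gene Fabp4 -0.88, while Kdr read 0.21 and Vwf 0.04. Esam and Fabp4 lay in uneven parts. With the local trend subtracted Esam read -0.44, Tek -0.47 and Fabp4 -0.68, while Eng stayed at -0.49. Tek was 7.94 and 7.90 in low salt mice 1 and 2, which shared an array, 8.85 and 9.07 in low salt mice 3 and 4, and 9.07 to 9.26 on normal salt. No single member passed over all genes, and 0 passed adjusted over the list alone, though Tek (-1.23, adjusted p = 0.0120), Eng (-0.52, adjusted p = 0.0421) and Esam (-0.75, adjusted p = 0.0423) passed without the array of low salt mice 3 and 4. Low salt then rests on 1 array, which cannot be told apart from diet. The list's call ended without normal salt mouse 1 (median -0.27, adjusted p = 0.0502), without the array of normal salt mice 1 and 2 (-0.19, adjusted p = 0.442) and in the Cy5 samples alone (-0.19, adjusted p = 0.110). With normexp fitted on all spots, chosen after seeing the data, the median was -0.10 (adjusted p = 0.00189). Markers of other cell types gave medians of -0.17 for smooth muscle and pericytes (adjusted p = 0.186), -0.09 for fibroblasts (adjusted p = 0.791), 0.16 for macrophages (adjusted p = 0.160) and -0.26 for nerve and Schwann cells (adjusted p = 0.102).

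Hypertrophy and fetal genes, the set re-expressed in a stressed ventricle, had a median difference of 0.33 over 16 genes, 9 of them higher (adjusted p = 0.0850; adjusted p = 0.560 with an estimated correlation). Of these 1, Rcan1, passed over all genes, and 3 passed adjusted over the list alone: Rcan1, Nppb and Ccn2. Nppb, the B-type natriuretic peptide gene, was 1.51 ± 0.28 (SE) higher, from 13.52 ± 0.29 to 15.03 ± 0.31 (SD, n = 4), in all 4 low salt mice, and missed the threshold (adjusted p = 0.0595). With the mouse number as a block it passed (adjusted p = 0.0292), as it did without normal salt mouse 4 (adjusted p = 0.00818), without the array of normal salt mice 3 and 4 (adjusted p = 0.00957) and without that of low salt mice 3 and 4 (adjusted p = 0.0445), where Ccn2 passed too (adjusted p = 0.0491). A fit without an array leaves its diet with 1 array, so array and diet cannot be told apart there. The Nppb probe lay in an uneven part, with a local difference of 0.22, and the Nppb value was 1.29 with the local trend subtracted. Acta1, the skeletal alpha-actin gene, read 1.41, Myh7, the slow myosin heavy chain gene, 1.46 in an uneven part with a local difference of 0.53, Gdf15 1.14 and Ccn2 0.56, while Nppa, the atrial natriuretic peptide gene, read 0.40 (adjusted p = 0.783) and Myh6 0.06, where a second Myh6 probe in an uneven part read -0.60. The list also holds atrial light chain genes, Myl4 at -1.97 and Myl7 at -1.08, and these varied widely between mice: Myl4 ranged over 4.46 log2 units across the 8 samples. The 9 atrial markers had a median of -0.36 and a mean of -0.71 (adjusted p = 0.164).

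With the mouse number as a block, 5 lists passed with the preset correlation: endothelial markers (adjusted p = 0.00390), macrophage markers (0.0252), fatty acid oxidation (0.0252), atrial markers (0.0252), and hypertrophy and fetal genes (0.0418). With an estimated correlation and no such block, hypertrophy and fetal genes had an adjusted p of 0.560 and the other 4 of 0.999. Without the block, fatty acid oxidation had a median of -0.12 over 32 genes (adjusted p = 0.126), with Cpt1b at -0.27 and Cpt2 at -0.68, where a second Cpt2 probe read 0.14. Cpt2 was 13.03 and 12.97 in low salt mice 1 and 2, against 14.08 and 13.81 in low salt mice 3 and 4, and passed without the array of the latter (-1.15, adjusted p = 0.0120). Low salt then rested on the array of mice 1 and 2 alone, which cannot be told apart from diet. Cytosolic ribosomal proteins had a median of -0.07 over 74 genes (adjusted p = 0.126).

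None of the lists for salt handling and the hormone systems that regulate it passed. Among their genes, none of 15 measured genes of the renin-angiotensin system passed, and the list's median was 0.04 (adjusted p = 0.954). Angiotensinogen (Agt) read 0.04 ± 0.12 (SE), the angiotensin receptor gene Agtr1a 0.06 ± 0.11 and Ace -0.37 ± 0.20. The members with the smallest p were Enpep, at 0.44 (limma adjusted p = 0.301), and Ctsg, at 0.60 (adjusted p = 0.468). Enpep and Ace lay in uneven parts and read 0.03 and -0.20 with the local trend subtracted. The mineralocorticoid receptor gene Nr3c2 read 0.05 ± 0.12. Over 19 corticosteroid targets the median was -0.09 (adjusted p = 0.358); the kinase gene Sgk1 read -0.76 (adjusted p = 0.313), Tsc22d3 -0.48 and Ddit4 -0.66, the last in an uneven part. Ddit4 passed with the mouse number as a block (adjusted p = 0.0310) and read -0.41 with the local trend subtracted (adjusted p = 0.388), and 1 target passed adjusted over the list alone. Without the array of low salt mice 3 and 4, Ace (-0.55, adjusted p = 0.0484), Sgk1 (-1.06, adjusted p = 0.0453) and Tsc22d3 (-0.57, adjusted p = 0.0291) passed. A single array then stands for low salt, so array and diet cannot be told apart in these calls.

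Sodium and chloride transport genes had a median of 0.01 over 28 genes (adjusted p = 0.954), and none passed over all genes, while 7 had an unadjusted p under 0.05. Scn3b, a channel beta subunit gene, read -1.11 ± 0.33 (SE; adjusted p = 0.254) and the anion exchanger gene Slc4a3 -0.54 in an uneven part. The Slc4a3 value was -0.23 with the local trend subtracted, and its other probes read -0.07 and -0.09. The sodium-calcium exchanger gene Slc8a1 read -0.23 and connexin 43 (Gja1) 0.33. None of these reached an adjusted p under 0.05 with all mice. Without the array of low salt mice 3 and 4, Scn3b (-1.66, adjusted p = 0.0190) and Slc4a3 (-0.81, adjusted p = 0.0138) passed. Low salt then rests on the array of mice 1 and 2 alone, so array and diet cannot be told apart. Scn3b was 7.37 and 7.25 in low salt mice 1 and 2, 8.33 and 8.47 in low salt mice 3 and 4, and 8.64 to 9.30 on normal salt. The 23 lists with an adjusted p over 0.2, which include calcium handling, sarcomere, glycolysis, oxidative phosphorylation and the extracellular matrix, had medians between -0.16 and 0.17. Markers of blood cells, lymphocytes, adipocytes, mast cells, mesothelium and skeletal muscle were among them.

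Read separately in each dye, as the series design describes, 352 genes were at least 1.5-fold higher and 248 at least 1.5-fold lower on low salt in both the Cy3 and the Cy5 mice. Cyp1a1 read -1.75 in the Cy3 and -2.27 in the Cy5 mice, and Nr1d1 read 1.13 and 1.07. Nppb read 1.76 and 1.26, and Pfkfb1, a glycolysis regulator gene, -1.21 and -1.17. Without the array of low salt mice 3 and 4 there were 478 higher and 679 lower genes. Without 1 mouse the lower count lay between 150 (normal salt mouse 2 left out) and 304 (low salt mouse 4 left out). With the local trend subtracted the balance turned, with 120 higher and 180 lower genes. No test stands behind these counts. Of the higher genes 83.2% lay in uneven parts, against 44.0% of the lower genes, which left 59 higher and 139 lower in even parts.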

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

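The comparison of spike-in spots with negative controls and the tests of the clock and atrial scores and of genes named after their values were seen, such as Arhgef19, were chosen after the data had been seen. Among 202 groups of 4 mice, 1 gene or score in 1 diet each, 6 held such a sample by the ratio of its gap to the group's range. Chance alone gives about 1 in 20, or 10.1 groups, so these 6 do not form a pattern.

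Low salt mouse 3 stood apart in Arhgef19 (gap over range 0.870), at a log2 intensity of 9.97 against 10.10 to 10.12 in the others, and in Ccn2 (0.891), at 12.58 against 13.04 to 13.10. Low salt mouse 2 stood apart in Krt8 (0.913), at 6.69 against 7.08 to 7.12. Low salt mouse 4 stood apart in Olfr1423 (0.943), at 6.19 against 6.47 to 6.49, where none of the low salt mice was well above background. Normal salt mouse 2 stood apart in Cidea (0.862), at 13.59 against 13.47 to 13.48, and normal salt mouse 4 in Cpt2 (0.944), at 13.98 against 14.19 to 14.21.

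Spike-in spots, which no comparison used, gave a signal in every sample. All 320 were well above background in each sample, and their median lay at least 5.83 log2 units above the median of the 153 negative control spots.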

How the results depend on the processing

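The alternatives that used even parts, subtracted the local trend, left out spots with an outlying background, fitted normexp on all spots or rebuilt the median signal minus background were chosen after seeing the data. Of the 19 settings run for single genes Cyp1a1 and Nr1d1 passed in 18, with ranges of -3.51 to -1.89 and 1.04 to 1.23, and missed as array means. Under the even parts Ralgapa2 read -0.29 and Rpl35 -0.64, from other probes of these genes, the Ralgapa2 probe being dim, and this choice of probe turned the sign. Against 144 genes, 616 changed with no array block, 235 with no dye term, 72 with arrays centred on their median, 34 with the scanner processed signal, 4 in even parts and 51 with the local trend subtracted, of which 4 and 38 were among the 144. No gene passed in limma with array means (1559 at an unadjusted p under 0.05), in the Cy3 (1848) or Cy5 samples (1244) alone or with no normalization between arrays (779), against 1985. The first 3 used 4 values, 1 per array, which leaves fewer degrees of freedom. With the replicate block, 228 genes and 5 lists passed; the named genes it added were Cx3cr1, Ddit4, Gsta3, Nppb and Pfkfb1, and it changed no other named call. Leaving out samples or arrays gave 52 to 1111 genes. Of single mice, normal salt 1, 2 and 3 gave 71, 64 and 53 and low salt 1 to 4 gave 57, 57, 71 and 52. Without the array of low salt mice 3 and 4 there were 1111, without that of 1 and 2 there were 68, and without normal salt mice 1 and 2 there were 244. Each of these fits leaves its diet with 1 array, which cannot be told apart from diet. Against 1 list, there were 3 with no array block, 6 with array means, 2 with no dye term, 3 in Cy3 and 4 in Cy5 samples, 2 with the processed signal, 5 with no filter on dim probes, 2 with probes above background in all samples, 6 in even parts, 7 with the local trend subtracted, 4 with normexp on all spots, 3 with median signal minus background, 0 with an estimated correlation (2 lists at an unadjusted p under 0.05), 0 with fry (2 lists) and 0 to 6 without a sample or array: 0 without normal salt mouse 1, 3 without 3 and 4 without 4, 4, 5, 4 and 6 without low salt mice 1 to 4, 2 without the array of normal salt mice 3 and 4 and 3 without that of low salt mice 1 and 2. Endothelial markers passed in 30 of 35 settings, and hypertrophy and fetal genes in 19. Against 600 genes apart in both dyes, there were 959 with the processed signal, 211 in even parts (65 higher, 146 lower), 300 with the trend subtracted, 156 with normexp on all spots, 2048 with a lower fold limit, 152 with a 2-fold limit and 462 to 1157 without a sample or array, the 1157 without the array of low salt mice 3 and 4. Apart from the choice of probe and the smaller sample numbers named, the cause was not tested. The series value table was not run as an alternative, since its rows could not be matched to probes. Genes near background, such as Olfr1423 and F8, are limited by signal.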

Other observations

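The tests of clock phase and atrial tissue, the comparison of the risen genes with random draws, the reading of brighter other probes alone, and all tests on even parts or with the local trend subtracted were chosen after the results had been seen. The genes named in the next 2 paragraphs that did not pass are given as values.

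Gsta3, a glutathione transferase gene, read -1.11 ± 0.23 (SE) on low salt, with all 4 low salt mice below all 4 normal salt mice and a second probe at -0.98, and missed the threshold (adjusted p = 0.0953). It passed with the mouse number as a block (adjusted p = 0.0238). Cx3cr1, the fractalkine receptor gene of macrophages, read 0.89 ± 0.22 (adjusted p = 0.160 without and 0.0383 with the block). Without low salt mouse 3 Cx3cr1 also passed (1.04, adjusted p = 0.0328). Its other 2 probes were higher as well. The 1 that read 0.66 lay in an uneven part and was dim, at a mean log2 intensity of 7.07. Pfkfb1 read -1.19 ± 0.29 (adjusted p = 0.155 without and 0.0144 with the block). Of 15 macrophage markers 14 were higher, though none passed over all genes and 1 passed adjusted over the list alone. Among unfolded protein response genes Manf read 0.73 and Creld2 0.52, in a list whose median was 0.01. The immediate early genes Ier3 and Ccn1 read -0.89 and 0.45. Without the array of low salt mice 3 and 4, Gsta3 (adjusted p = 0.0220), Cx3cr1 (0.0177), Pfkfb1 (0.0449), Manf (0.0437), Creld2 (0.0221) and Ier3 (0.0247) passed. These calls set 1 low salt array against normal salt, so array and diet cannot be told apart in them.

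In all parts together, nerve and Schwann cell markers had a median of -0.26 over 10 genes, 7 of them lower, and the list passed in even parts with the preset correlation (adjusted p = 0.00223), though not with an estimated one (adjusted p = 0.355). Dbh, the noradrenaline-forming enzyme gene, read -0.53 ± 0.11 (adjusted p = 0.103), Sox10 -0.41 and S100b -0.37. Th, the rate-limiting enzyme gene of catecholamine synthesis, read 0.37 in an uneven part.

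The first pattern was the gathering of genes higher on low salt in uneven parts of the arrays. Of the risen genes 94.2% lay there, against at most 42.3% in 10000 random draws of as many genes, which argues against a chance gathering of their probes. Spots of 221 probes with copies in both uneven and even parts of the same array received the same RNA, and their difference followed the local trend with a slope of 1.07 (bootstrap interval 1.01 to 1.14), as an uneven signal needs. For 29 risen genes with another probe in an even part, those probes had a median log2 difference of 0.012 (interval -0.10 to 0.08), against 0.95 at the called probes, and for the 16 of them whose other probe had a log2 intensity of at least 8 the interval was -0.15 to 0.09, against 0.99, which argues against a change in these transcripts as a set. An uneven signal, brighter on both low salt arrays than on both normal salt arrays, may account for part or all of the rises. At the called probes the local difference had a median of 0.52 against a rise of 0.90. These genes were chosen for a large rise, so the gap cannot show how much of the rises an uneven signal leaves. Genes with no other probe stay open.

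The second pattern was in the circadian clock list, whose median was -0.16 over 20 genes and which did not pass (adjusted p = 0.954). Arntl was 8.44 ± 0.20 (SD, n = 4) on low salt and 7.19 ± 0.33 on normal salt (limma adjusted p = 0.0900), Per2 6.92 ± 0.29 and 7.99 ± 0.35 (adjusted p = 0.143), and 5 list members passed adjusted over the list alone. Genes that peak around lights-on (Arntl, Clock) minus 7 that peak late in the light phase (Per1, Per2, Per3, Dbp, Tef, Hlf, Usp2) differed by 1.05 between the diets, which describes the pattern in genes whose values had been seen and tests no shift in phase. Subtracting the local trend left 0.987 of this difference, which argues against an uneven signal. A difference in clock phase, from diet or from the hour of collection, which the sources used here do not give, stays open: Nr1d1, which peaks in the light phase and was left out of the score, moved in the same direction as Arntl, and Dbp read 0.30.

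The third pattern was the spread of atrial markers between mice. Sln, an atrial calcium pump regulator, ranged over 5.03 log2 units, and Myl4 read 11.01 and 13.98 in low salt mice 1 and 2 on the same array. Within diet and dye the 9 markers had a mean pairwise correlation of 0.503, above 99.9% of 9986 random lists of the same size and brightness, and 1.02 of the spread between mice was left after the local trend was subtracted, which argues against an uneven signal. Atrial tissue in some of the samples may account for it; 3 of the 9 markers (Nppa, Myl4 and Myl7) are also fetal genes that ventricle can express, and that explanation was not tested. The diets differed by -0.71 in the mean marker level, which missed the threshold (exact permutation p = 0.2).

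Diet followed whole arrays, and 34 of the 35 splits of the 8 mice into 4 and 4 could be fitted. The real split called 144 genes and the highest other 28, so 1 of 34 splits gave as many genes. Other groupings of the mice thus gave fewer. Splits that cut arrays do not compare with the real one, and an uneven signal that follows diet would also set it apart. This count therefore cannot tell diet from the arrays. Only 3 splits keep each array whole, too few for a share under 0.05. The split that joined normal and low salt mice 1 and 2 gave the 28. Among the 8 splits that part all 4 same-numbered pairs, also too few for such a share, the highest other gave 0 genes. The remaining splits left some pairs together. In even parts the real split called 4 genes, 1 of 34 splits gave as many and the highest other gave 0. For gene lists the real split gave 1, 32 of 34 splits gave as many and the highest other gave 15, so a chance result was not excluded there.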
